A study of Mus musculus with 26 samples.

How the data were processed

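Gene expression was measured on 26 one-colour arrays, each hybridised with biotin-labelled cRNA from 1 culture of mouse neural stem and progenitor cells. The cells came from the telencephalon at postnatal day 0 and were treated after passage 3 for 4 h with 100 nM dexamethasone (Dex, a synthetic glucocorticoid) or with the ethanol vehicle. The labels give 6 wild-type (WT) cultures, numbered 1 to 6, and 7 SOX2 knockout (KO) cultures, numbered 7 to 13, with 1 vehicle and 1 Dex array for each number. The labels say that both sexes were used but give no sex for any array.

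The deposited values were taken as log2 expression. The unit was read from the values, which lie between 2.22 and 19.81 with 2 decimals, since neither the base of the logarithm nor the authors' normalization is stated. The upper quartiles of the arrays ranged from 9.38 to 10.43, so the 26 arrays had not been brought to 1 common distribution. The deposited table holds 22206 transcript clusters. Of these, 19572 carry 1 gene symbol, none carries several, and 2634 carry none and stayed out of the tests. Where a gene had more than 1 transcript cluster (55 genes), the one of highest mean over all arrays was used, which left 19505 genes. All 19572 named transcript clusters were matched to the reference through their Entrez identifier, and no symbol changed.

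Comparisons were made with limma 3.58.1 in R 4.3.3. A model with 1 mean for each of the 4 groups was fitted to all 26 arrays, followed by empirical Bayes moderation and Benjamini-Hochberg adjustment over all genes, with an adjusted p threshold of 0.05 and no fold minimum. The 5 contrasts were Dex against vehicle in WT and in SOX2 KO, SOX2 KO against WT in vehicle and in Dex, and the difference between the Dex effects of the genotypes. Errors of fold changes are moderated standard errors (SE), and errors of group levels are standard deviations (SD). For arrays, their number limits the precision.

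For 32 gene lists holding 614 genes, camera from limma was run with a preset correlation between genes of 0.01, adjusted over the 32 lists of a contrast. Camera with an estimated correlation and fry were run beside it. For the glucocorticoid-induced and the glucocorticoid-repressed list, the mean Dex minus vehicle difference of each culture was compared between genotypes by an exact two-sided permutation test over all 1716 splits of the 13 cultures. Lists, tests, the rule for named genes and a first set of alternatives were fixed before the data were examined. That rule takes in each comparison the 8 largest rises and the 8 largest falls among genes past the threshold, or the 5 genes of smallest p where none passed. It adds up to 4 members of smallest p from each list described, and Sox2, Nr3c1, Fkbp5, Tsc22d3, Sgk1 and Per1 in every comparison. Symbols of predicted loci were counted and not named. Since no gene passed in WT, the rule was also applied to the fit with the culture as a block and culture 4 left out, a choice made after the data were seen.

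Whether the numbers pair the arrays was checked on the profiles left after removing group means. The vehicle and Dex arrays of the same number correlated at 0.31 to 0.73, and the median with other Dex arrays of the genotype was -0.24. Removing group means itself lowers the correlation between different cultures. For 22 of the 26 arrays the best match was the array of the same number. The misses were all in SOX2 KO, in cultures 9, 11, 12 and 13. Their pairs correlated at 0.31 to 0.40, against 0.49 or above in WT, so the pairing is less certain there. Fits with the culture as a block are therefore given beside the Dex results wherever they change a call or move a count by more than 1.5 times. The same profiles, averaged per culture and clustered on correlation, gave 3 array clusters, which the labels do not mention and which were used as a covariate in an alternative fit chosen after the data were seen.

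The other alternatives were quantile normalization, median centring, a filter on genes of low mean, only the arrays of the 2 groups compared, a trended and robust prior, array weights, the mean of a gene's transcript clusters, leaving out each culture, and a minimum fold change of 1.5. A covariate for the level of Xist was planned and not run, because no transcript cluster carries that symbol. The level of the Y-linked gene Eif2s3y took its place, chosen after the data were seen. Leaving out culture 4, culture 12 or both, with and without the block, and leaving Sox2 out of the gene lists that hold it, were added as well.

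The scripts were tested on simulated data with 19505 genes, of which 100 changed by 1 and 100 by 2 log2 units. For Dex in WT the fit recovered 54% and 99% of these, and with the culture as a block 86% and 100%. For Dex in SOX2 KO it recovered 57% and 100%, and 87% and 100% with the block. For SOX2 KO against WT it recovered 49% and 99% in vehicle and 50% and 100% in Dex. For the difference of the Dex effects it recovered 10% and 84%, and 36% and 99% with the block. The simulated genes were independent, with equal parts of the variance from culture and array. No array clusters and no culture with a reversed response were simulated, so these shares can overstate the recovery in the real data.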

Results

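The 26 arrays came from 13 cultures of neural stem and progenitor cells, 6 WT and 7 SOX2 KO, each with 1 array after 4 h of vehicle and 1 after 4 h of 100 nM Dex. Array medians lay between 6.44 and 6.84 log2 units. By overall profile the cultures fell into 3 array clusters that the labels do not mention. Cluster 1 held 3 WT and 2 SOX2 KO cultures (1, 2, 3, 7 and 8), cluster 2 held 1 WT and 2 SOX2 KO cultures (4, 10 and 12), and cluster 3 held 2 WT and 3 SOX2 KO cultures (5, 6, 9, 11 and 13). The clusters also differed in signal distribution. The upper quartile was 10.09 to 10.43 on the arrays of cluster 1 and at most 9.79 on those of clusters 2 and 3, which overlapped in this value. How far the clusters reflect the scaling of the arrays was not tested. The Y-linked gene Eif2s3y was at 11.82 or above in 3 of 6 WT and 2 of 7 SOX2 KO cultures and at 4.46 or below in the others.

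Sox2, which encodes a transcription factor of neural stem cells, was the gene with the largest difference between genotypes. Its level was 13.40 ± 0.70 (SD, n = 6) in WT vehicle arrays and 12.96 ± 0.56 in WT Dex arrays. In SOX2 KO cultures it was 4.65 ± 0.51 (SD, n = 7) in vehicle and 4.79 ± 0.89 in Dex. All SOX2 KO arrays lay between the 3.02 and 48.1 percentiles of their own array, and all WT arrays between the 88.7 and 96.9 percentiles. Dex left no called change of Sox2 in either genotype, with log2 fold changes of -0.44 ± 0.36 (SE) in WT and 0.14 ± 0.34 in SOX2 KO.

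**Figure D1:**
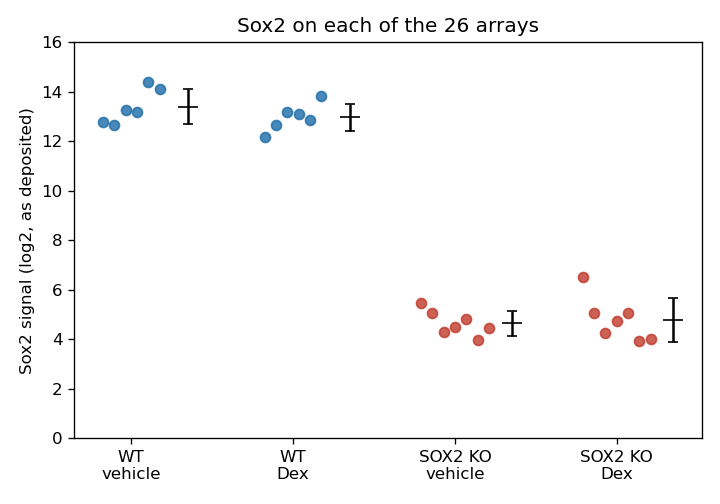
Sox2 signal (y axis, log2 as deposited) on each array of the 4 groups (x axis), with 1 point per culture and the group mean ± SD in black. WT arrays average 13.40 in vehicle and 12.96 in Dex, and SOX2 KO arrays 4.65 and 4.79.

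The series is titled as a study of genomic glucocorticoid action, and its first comparison asks which genes respond to Dex in WT cells. The mean of the glucocorticoid-induced list was higher in the array labelled Dex in 5 of the 6 WT cultures, with 29 to 41 of its 46 measured members higher, and lower in culture 4, with 8 members higher. Fkbp5, a co-chaperone of the glucocorticoid receptor, was higher by 1.27 to 1.87 log2 units in cultures 1, 2, 3, 5 and 6 and differed by -2.03 in culture 4. The clock gene Per1 was higher by 1.91 to 3.04 in the same 5 cultures and differed by -2.74 in culture 4. Fam107a, a gene of actin dynamics, was higher by 4.61 to 5.76 in the 5 cultures and differed by -6.83 in culture 4. With all 6 cultures no gene passed in limma, and 188 genes had an unadjusted p under 0.05 (133 higher and 55 lower). Chance would give 975 with independent arrays, which is no baseline here. The 2 arrays of a culture correlate, and this fit leaves out their pairing. The genes of smallest p were Fam107a (3.38 ± 0.89, SE, n = 6), Sprr2j-ps (1.08 ± 0.30), the proto-oncogene Mycn (-0.86 ± 0.24), the potassium channel gene Kcnn2 (1.80 ± 0.51) and Per1 (1.503 ± 0.442), each with an adjusted p of 1. With the culture as a block the count was again 0 (755 genes at an unadjusted p under 0.05).

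**Figure D2:**
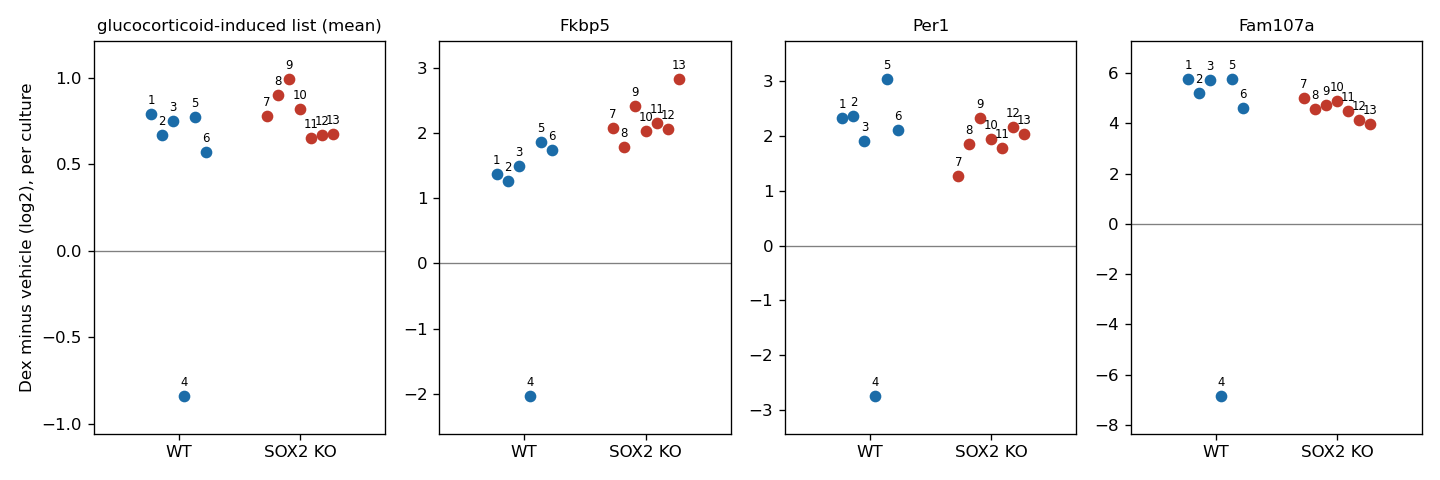
Dex minus vehicle difference (y axis, log2) of each culture, by genotype (x axis) and with the culture number beside each point, for the mean of the glucocorticoid-induced list and for Fkbp5, Per1 and Fam107a. Culture 4 lies at -0.84, -2.03, -2.74 and -6.83, and all the other 12 cultures lie above 0.

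Without culture 4 and with the culture as a block, 31 genes rose and 2 fell in the other 5 WT cultures. Fam107a rose by 5.42 ± 0.19 log2 units (SE, n = 5, adjusted p = 5.47e-11), Kcnn2 by 2.58 ± 0.24, Per1 by 2.35 ± 0.18 (adjusted p = 3.35e-06) and the chloride channel gene Cftr by 2.25 ± 0.28. The transcription factor gene Klf9 rose by 2.05 ± 0.20, Map7d2 by 1.76 ± 0.20, the receptor kinase gene Mertk by 1.62 ± 0.31 and Tsc22d3, an anti-inflammatory glucocorticoid target, by 1.60 ± 0.19. Fkbp5 rose by 1.55 ± 0.16 (adjusted p = 0.000127). Each of these was higher in 5 of 5 cultures. The genes that fell were Arntl2, a relative of the clock gene Bmal, at -0.93 ± 0.17 (adjusted p = 0.0381), and Mycn at -0.92 ± 0.16 (adjusted p = 0.0150), both lower in 5 of 5 cultures. Neither Sgk1 (-0.04 ± 0.19, higher in 2 of 5 cultures), a kinase gene often induced by glucocorticoids, nor Nr3c1 (-0.28 ± 0.21), the gene of the glucocorticoid receptor, passed. Leaving out culture 4 without the block gave 7 genes, all higher.

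Among the gene lists, the glucocorticoid-induced list (46 of 47 genes measured) was higher in WT Dex arrays by a mean of 0.45 and a median of 0.32 log2 units (camera adjusted p = 6.23e-17). That call held with an estimated correlation (adjusted p = 0.0203) and not in fry (adjusted p = 0.347). With array cluster as a covariate the list passed in camera (adjusted p = 1.07e-14) but not with an estimated correlation (adjusted p = 0.0704). None of its members passed over all genes, and 3 passed adjusted over the list alone (Per1, Klf9 and Fam107a). With the block and without culture 4, 11 members passed over all genes and 21 adjusted over the list alone, and the mean was 0.71. They included the stress gene Sesn1 (1.26 ± 0.16), the lipid transporter gene Mfsd2a (1.24 ± 0.21) and the metallothionein gene Mt2 (1.29 ± 0.23). The neural stem and progenitor list (25 genes measured) had a lower mean in Dex, -0.13 with a median of -0.10 (camera adjusted p = 0.0230). That call was lost with an estimated correlation (adjusted p = 0.659) and with Sox2 left out of the list (mean -0.11, adjusted p = 0.0527). None of its members passed, and those of smallest p were Msi1 (-0.45 ± 0.18, SE) and Pax6 (-0.38 ± 0.24). The glucocorticoid-repressed list (20 genes measured) had a mean of -0.09 and did not pass (adjusted p = 0.195).

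In SOX2 KO cultures, Dex raised 10 genes and lowered none in limma (553 genes at an unadjusted p under 0.05). Fam107a rose by 4.54 ± 0.83 log2 units (SE, n = 7, adjusted p = 0.0210). Hif3a, a hypoxia-inducible factor subunit, rose by 2.91 ± 0.31 (adjusted p = 4.58e-06), Cftr by 2.71 ± 0.52, Mt2 by 2.39 ± 0.37, Klf9 by 2.24 ± 0.38 and Fkbp5 by 2.20 ± 0.33 (adjusted p = 0.00229). Zbtb16, a zinc finger transcription factor gene, rose by 2.06 ± 0.38 and Mgll, a lipase gene of endocannabinoid breakdown, by 1.73 ± 0.32. Map7d2 and Adamts9 passed as well. Each of the 8 genes with a value was higher in 7 of 7 cultures, and all 10 had the same sign in the 3 array clusters. Of all genes 29.1% did, which is no baseline for the 10, since they were selected on these cultures. Per1 (1.92 ± 0.41, adjusted p = 0.0967), Tsc22d3 (1.05 ± 0.34) and Sgk1 (0.51 ± 0.43) were each higher in 7 of 7 cultures and did not pass.

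The count in SOX2 KO moved with the fit. The culture as a block gave 14 genes, all higher, of which 7 were among the 10. The 3 that it lost were Fam107a (4.54 ± 1.02, adjusted p = 0.142), Zbtb16 (2.06 ± 0.38, adjusted p = 0.0550) and Map7d2. The block without culture 4, a WT culture that enters through the shared variance, gave 46 higher and 3 lower, and array cluster as a covariate gave 23 higher and 2 lower. Leaving out any 1 SOX2 KO culture gave 3 to 5 genes. In the block without culture 4, Per1 (adjusted p = 2.33e-06) and Tsc22d3 (adjusted p = 0.00501) passed with the same fold changes, while Pde1b, a phosphodiesterase gene, fell by 1.13 ± 0.16, Cntnap4 by 0.90 ± 0.15 and Prrx1 by 0.77 ± 0.15.

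The glucocorticoid-induced list was higher in SOX2 KO Dex arrays by a mean of 0.79 and a median of 0.44 (camera adjusted p = 7.23e-35). That call held with an estimated correlation (adjusted p = 0.000295) and in fry (adjusted p = 0.00101). Of its 46 measured members, 6 rose over all genes and 19 adjusted over the list alone, none fell, and 27 did not pass. With the block and without culture 4, the fit that gave 11 and 21 in WT, 16 passed over all genes and 23 adjusted over the list alone, and with array cluster as a covariate 9 and 21 did. Among the 19 were the clock gene Per1, the inhibitor of NF-kappa-B Nfkbia (1.39 ± 0.42) and the lipocalin gene Lcn2 (1.36 ± 0.33). The glucocorticoid-repressed list had a mean of -0.14 (adjusted p = 0.237), with Nr3c1 (-0.57 ± 0.18) and the proto-oncogene Myc (-0.72 ± 0.23) lower adjusted over the list alone. With the block and without culture 4 only Myc passed adjusted over that list (limma adjusted p = 0.0332). The circadian clock list (18 genes) did not pass (mean 0.19, adjusted p = 0.0600), while its members Per1 and Per2 (1.22 ± 0.28) passed adjusted over the list alone. With the culture as a block camera also called the extracellular matrix and replication lists as lower (adjusted p = 0.0292 for each), which did not pass without the block (adjusted p = 0.0849 and 0.0600). With an estimated correlation neither passed without the block (adjusted p = 0.878 and 0.911) or with the block and without culture 4 (adjusted p = 0.410 and 0.563).

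**Figure D3:**
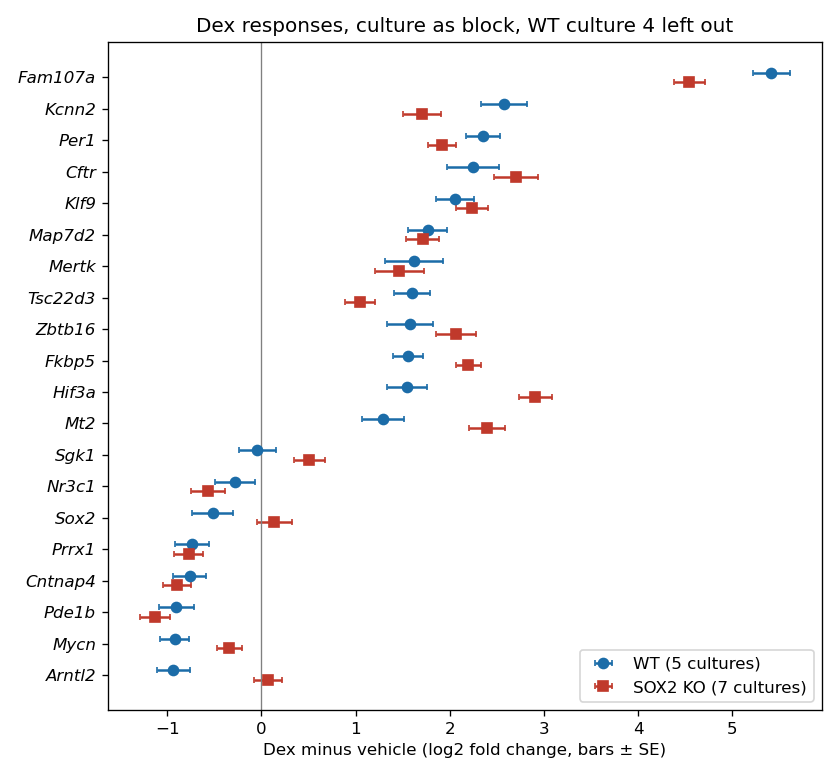
Log2 fold change of Dex against vehicle (x axis, bars ± SE) of 20 genes named above (y axis) in WT (circles, 5 cultures) and SOX2 KO (squares, 7 cultures), from the fit with the culture as a block and culture 4 left out. Fam107a has the largest rise plotted, 5.42 in WT and 4.54 in SOX2 KO, and Sgk1, Nr3c1 and Sox2 passed in neither genotype.

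Whether the genotypes differ in their Dex response was tested directly. Over all genes none passed this test in limma (140 genes at an unadjusted p under 0.05). None passed with the culture as a block either (688 genes), or with the block and without culture 4 (644 genes). The genes of smallest p were Hif3a, with a Dex effect larger in SOX2 KO by 1.89 ± 0.46 log2 units (SE), Mt2 (1.66 ± 0.54), Vmn1r191 (1.39 ± 0.42), Olfr389 (1.27 ± 0.41) and Hsd3b6 (0.95 ± 0.30), each with an adjusted p of 1.00. Fkbp5 differed by 1.24 ± 0.49, and by 0.64 ± 0.21 with the block and without culture 4, and passed in neither fit. Hif3a differed by 1.37 ± 0.28 in that second fit. Adjusted over the glucocorticoid-induced list alone, Hif3a passed (adjusted p = 0.0126), and also with the block and without culture 4 (adjusted p = 0.00676) and with array cluster (adjusted p = 0.00669). With the block and without culture 4, Mt2 (1.10 ± 0.30, adjusted p = 0.0423) and Fam107a (-0.87 ± 0.25, adjusted p = 0.0471) passed adjusted over that list as well. The sign for Fam107a turned with culture 4, since with all cultures its Dex effect was larger in SOX2 KO by 1.17 ± 1.22 and did not pass. In simulated data, which held no array clusters and no reversed culture, the test recovered 10% of differences of 1 log2 unit and 84% of differences of 2.

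The mean response of the glucocorticoid-induced list was 0.45 ± 0.64 (SD, n = 6) in WT and 0.79 ± 0.13 (SD, n = 7) in SOX2 KO cultures. The difference of 0.33 did not pass the exact two-sided permutation test (p = 0.0927, adjusted over the 2 lists 0.185). Without culture 4 the WT mean was 0.71 ± 0.09 (SD, n = 5) and the difference 0.07 (exact permutation p = 0.307). Within array clusters 1 and 3 the difference was 0.10 and 0.10, and in cluster 2, whose only WT culture is culture 4, it was 1.58. Camera called the list in the test of the difference (adjusted p = 7.28e-07), and that call was lost with an estimated correlation (adjusted p = 0.600) and with the block and without culture 4 (adjusted p = 0.363). For the glucocorticoid-repressed list the responses were -0.09 ± 0.12 in WT and -0.14 ± 0.14 in SOX2 KO (exact permutation p = 0.485, adjusted 0.485). In clusters 1, 2 and 3 this difference was 0.04, -0.14 and -0.07.

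Across the 19505 genes, which are not independent replicates, the Dex fold changes of the genotypes correlated with a Pearson coefficient of 0.285 and a Spearman coefficient of 0.219. Over the 10 genes called in SOX2 KO, which were selected on their effect there, the Pearson coefficient was 0.891 and the Spearman coefficient 0.612. With the block and without culture 4, the genotypes shared 27 of the 31 genes raised in WT and the 46 raised in SOX2 KO, against 0.0731 for independent lists. The shared genes included Fam107a, Kcnn2, Per1, Per2, Cftr, Klf9, Fkbp5, Tsc22d3, Zbtb16, Hif3a and Mt2. None of the 2 and 3 genes that fell passed in both genotypes. Pde1b (-0.91 ± 0.19), Cntnap4 (-0.76 ± 0.18) and Prrx1 (-0.74 ± 0.18) were lower in 5 of 5 WT cultures without passing, and Mycn (-0.34 ± 0.13) was lower in 7 of 7 SOX2 KO cultures.

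The comparison of SOX2 KO with WT cells in vehicle asks which genes differ without Dex. In limma 37 genes were higher and 72 lower in SOX2 KO (1009 at an unadjusted p under 0.05). The largest rises were Clic5, a chloride intracellular channel gene (3.42 ± 0.51, SE, adjusted p = 0.000290), the transcription factor gene Runx1 (2.35 ± 0.44), the secretogranin gene Scg2 (2.29 ± 0.45), the matrix gene Svep1 (1.83 ± 0.32), Id2 (1.81 ± 0.43), Ecrg4 (1.76 ± 0.26), the phosphodiesterase gene Pde3a (1.64 ± 0.27) and Lef1, a transcription factor gene of Wnt signalling (1.64 ± 0.37). After Sox2 (-8.75 ± 0.35, adjusted p = 3.61e-17), the largest falls were Fndc3c1 (-4.80 ± 0.31, adjusted p = 1.20e-11), the vesicle GTPase gene Rab3b (-3.31 ± 0.64), the lactoperoxidase gene Lpo (-2.93 ± 0.29), the mitochondrial glutamate carrier gene Slc25a18 (-2.64 ± 0.33), Epb41l4a (-2.56 ± 0.34), the potassium channel gene Kcnj16 (-2.52 ± 0.27) and Paqr8 (-2.31 ± 0.40). For Clic5, Runx1, Svep1, Id2, Ecrg4, Lef1, Sox2, Fndc3c1, Lpo, Slc25a18, Epb41l4a and Kcnj16, all 7 SOX2 KO cultures lay beyond all 6 WT cultures.

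All 109 genes had the same sign within each of the 3 array clusters, as 34.9% of all genes did. The 109 were selected on these same cultures, which favours 1 sign throughout, so the share of all genes is no baseline for them. In clusters 1, 2 and 3 the difference was 4.03, 5.32 and 2.03 for Clic5, -3.89, -6.64 and -4.57 for Fndc3c1, and -0.80, -4.86 and -4.52 for Rab3b, with culture 4 as the only WT culture of cluster 2. For Paqr8, which Dex raised in both genotypes in the block fit without culture 4, it was -1.90, -4.36 and -1.37. The vehicle array of culture 4 had a glucocorticoid-induced list level of 8.95, above the other WT vehicle arrays (7.94 to 8.52). How much of the Paqr8 difference comes from that array was not tested. With array cluster as a covariate all 109 passed in the same direction, and the count was 188 higher and 188 lower. Array weights gave 378 genes (83 higher and 295 lower), quantile normalization 168 (70 and 98), and leaving out the Dex array of culture 12 gave 164 (53 and 111).

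**Figure D4:**
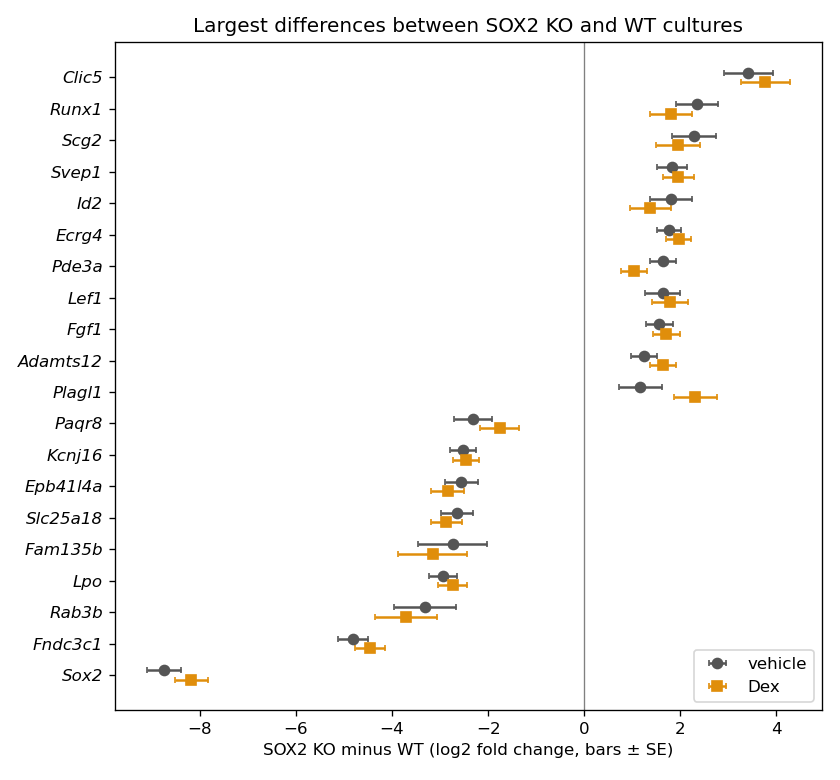
Log2 fold change of SOX2 KO against WT (x axis, bars ± SE) of 20 genes with the largest called differences (y axis) in vehicle (circles) and in Dex (squares), 7 SOX2 KO and 6 WT cultures. Sox2 lies at -8.75 in vehicle and -8.17 in Dex, and every gene plotted has the same sign in both.

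By gene list, 4 of the 20 measured astrocyte genes were lower in SOX2 KO vehicle arrays over all genes and none was higher. These were Slc1a2, an astrocytic glutamate transporter gene (-2.03 ± 0.35), the bicarbonate transporter gene Slc4a4 (-2.001 ± 0.337), the aldolase gene Aldoc (-1.71 ± 0.22) and the lipid gene Acsbg1 (-0.90 ± 0.17). Id3, an inhibitor of differentiation, was higher adjusted over the list alone (1.23 ± 0.45, adjusted p = 0.0413). The list's mean was -0.28 and its median -0.14 (camera adjusted p = 0.00892, and adjusted p = 0.533 with an estimated correlation). With array cluster as a covariate the astrocyte list no longer passed (adjusted p = 0.0858), its mean was -0.12 and its median 0.07. In that fit the 4 genes passed as lower, and Id3 (1.40 ± 0.39) and Cd44 (1.13 ± 0.33) passed as higher adjusted over the list alone. The list of gap junction and ion transport genes (13 measured) had a mean of -0.54 (adjusted p = 8.83e-06, and adjusted p = 0.235 with an estimated correlation), with 12 members lower. Of these Kcnj16 passed over all genes, and Kcnj10 (-1.24 ± 0.35) passed adjusted over the list alone. The list of genes of the start of DNA replication (23 measured) had a mean of -0.31 (adjusted p = 8.83e-06, and adjusted p = 0.489 with an estimated correlation). Of these 22 were lower, none passed over all genes, and Tk1 (-0.70 ± 0.20) passed adjusted over the list alone. The neural stem and progenitor list (25 measured, mean -0.40, median -0.12) passed in camera (adjusted p = 0.0403, and adjusted p = 0.489 with an estimated correlation). The list holds Sox2 itself, and over the other 24 members the mean was -0.05 and the list did not pass (adjusted p = 0.558). Its only member past the threshold over all genes was Sox2, and Egfr (-0.92 ± 0.26) and the matrix gene Tnc (1.25 ± 0.39, higher) passed adjusted over the list alone.

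Lists with a higher mean in SOX2 KO vehicle arrays were the immediate early and MAPK feedback list (30 measured, mean 0.25, adjusted p = 7.01e-05) and the BMP and TGF-beta list (21 measured, mean 0.27, adjusted p = 0.00892). Both calls were lost with an estimated correlation (adjusted p = 0.489 for each). None of the immediate early genes passed over all genes, and the phosphatase gene Dusp4 (1.24 ± 0.31) passed adjusted over the list alone. In the BMP list Id2 was higher while Bmp7, a secreted ligand, was lower (-1.56 ± 0.34), and Id1 (2.13 ± 0.59) passed adjusted over the list alone. Camera also called oxidative phosphorylation (mean -0.19, adjusted p = 0.0199), hypoxia and glycolysis (mean -0.25, adjusted p = 0.0403) and ribosomal proteins (mean 0.11, adjusted p = 0.0403), with no member past the threshold over all genes. With an estimated correlation these had adjusted p of 0.489, 0.542 and 0.489. Hypoxia and glycolysis (adjusted p = 0.0623), ribosomal proteins (adjusted p = 0.140) and the neural stem list (adjusted p = 0.0811) no longer passed with array cluster as a covariate, where their means were -0.17, 0.09 and -0.34. Without cultures 4 and 12, 3 of the 9 lists called in vehicle passed. Fry called the gap junction list, the neural stem list and the SOX2 network list (adjusted p = 0.0269 for each), of which the last 2 hold Sox2 and the last is not among the 9.

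In Dex, 36 genes were higher and 74 lower in SOX2 KO than in WT (1475 at an unadjusted p under 0.05). Among the largest were again Clic5 (3.77 ± 0.51, SE, adjusted p = 6.42e-05), Ecrg4 (1.97 ± 0.26), Svep1 (1.96 ± 0.32), Scg2 (1.96 ± 0.45) and Lef1 (1.79 ± 0.37). Plagl1, an imprinted zinc finger gene (2.31 ± 0.45), the growth factor gene Fgf1 (1.71 ± 0.28) and the protease gene Adamts12 (1.64 ± 0.28) were the other large rises. The falls were led by Sox2 (-8.17 ± 0.35), Fndc3c1 (-4.45 ± 0.31), Rab3b (-3.71 ± 0.64), Fam135b (-3.16 ± 0.72, adjusted p = 0.0308), Slc25a18 (-2.87 ± 0.33), Epb41l4a (-2.84 ± 0.34), Lpo (-2.74 ± 0.29) and Kcnj16 (-2.46 ± 0.27). The vehicle and Dex comparisons shared 21 higher and 51 lower genes, against 0.0683 and 0.273 for independent lists, and no gene was called in opposite directions. The same cultures stand in both comparisons, so they are not independent.

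All 110 genes had the same sign within each array cluster, as 31.8% of all genes did, but the 110 were likewise selected on these cultures. For Clic5 the differences in clusters 1, 2 and 3 were 4.75, 4.21 and 2.44, for Fndc3c1 -4.36, -4.24 and -4.79, and for Fam135b -4.25, -2.16 and -1.45. For Plagl1 they were 2.21, 4.13 and 1.66. In the block fit without culture 4, Dex raised Plagl1 in SOX2 KO, and the gene was not called in WT. The Dex array of culture 4, the only WT culture of cluster 2, had a low glucocorticoid-induced list level. How much of the Plagl1 difference comes from that array was not tested. With array cluster as a covariate all 110 passed, among 187 higher and 210 lower. Array weights gave 561 genes (117 higher and 444 lower), quantile normalization 171 (78 and 93), and a fit on the 2 groups alone 72 (25 and 47). Leaving out WT culture 1 gave 69 and leaving out SOX2 KO culture 13 gave 71.

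The 4 astrocyte genes were lower in Dex as well, with log2 fold changes of -2.08 ± 0.35 for Slc1a2, -1.72 ± 0.34 for Slc4a4, -1.40 ± 0.22 for Aldoc and -0.81 ± 0.17 for Acsbg1. The astrocyte list had a mean of -0.32 (camera adjusted p = 0.0218), and as a list did not pass with array cluster as a covariate (adjusted p = 0.123). The replication list had a mean of -0.40 (adjusted p = 4.16e-06), with 22 of 23 members lower and Cdt1 (-0.87 ± 0.25) and Uhrf1 (-0.67 ± 0.21) past the threshold adjusted over the list alone. The immediate early list had a mean of 0.26 (adjusted p = 1.24e-05), with Dusp4 (1.20 ± 0.31) and Spry4 (0.81 ± 0.22) past the threshold adjusted over the list alone. The gap junction and ion transport list had a mean of -0.49 (adjusted p = 0.00183). The glucocorticoid-induced list was higher by a mean of 0.21 (adjusted p = 0.000474), with Hif3a (1.60 ± 0.32) and the transcriptional repressor gene Bcl6 (1.04 ± 0.23) past the threshold over all genes. In this comparison the Dex array of culture 4, in which the list stood at 8.11 against 8.60 to 9.27 in the other WT Dex arrays, is among the WT values. Camera also called oxidative phosphorylation (mean -0.27, adjusted p = 0.00268), mitosis (mean -0.27, adjusted p = 0.0117) and hypoxia and glycolysis (mean -0.32, adjusted p = 0.0436). Mitosis and hypoxia and glycolysis no longer passed with array cluster as a covariate (adjusted p = 0.0512 for each), where their means were -0.17 and -0.24. None of these 8 calls held with an estimated correlation, where the adjusted p of the glucocorticoid-induced list was 0.564 and that of the astrocyte list 0.618. None of the 8 passed in fry, which called the neural stem list (adjusted p = 0.0392) and the SOX2 network list (adjusted p = 0.0266), both of which hold Sox2.

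Nr3c1 and the glucocorticoid target genes named in every comparison passed no test between the genotypes. In vehicle the differences were 0.15 ± 0.19 (SE) for Nr3c1, -0.63 ± 0.34 for Fkbp5, -0.83 ± 0.36 for Tsc22d3, -0.54 ± 0.44 for Sgk1 and -0.02 ± 0.43 for Per1. In Dex they were -0.09 ± 0.19 for Nr3c1, 0.61 ± 0.34 for Fkbp5, -0.84 ± 0.36 for Tsc22d3, 0.01 ± 0.44 for Sgk1 and 0.39 ± 0.43 for Per1. Culture 4 is among these WT values and is the only WT culture of cluster 2. In clusters 1, 2 and 3 the vehicle difference was -0.13, -1.91 and -0.36 for Fkbp5, -0.15, -2.59 and -0.40 for Tsc22d3, -1.66, 0.97 and -0.37 for Sgk1 and 0.60, -1.61 and 0.34 for Per1. In Dex it was 0.42, 2.17 and 0.31 for Fkbp5, -0.89, 0.22 and -0.92 for Tsc22d3, -1.05, 1.67 and 0.02 for Sgk1, and for Per1 3.19 in cluster 2 but -0.03 and -0.19 in clusters 1 and 3.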

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

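The tests on culture 4, on the list difference without culture 4, on the array clusters and on the share of calls on chromosome 3 were chosen after the results were seen. Of 32 groups of samples checked for a sample far from the others, 5 held one, while chance alone gives about 1 in 20 for independent groups. The groups overlap, however. Apart from 1 array of culture 12, the 5 are all the Dex response of WT culture 4, in the glucocorticoid-induced list and in members of that list.

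WT culture 4 stood apart from the other WT cultures in the Dex minus vehicle difference of the glucocorticoid-induced list (-0.84 against 0.57 for the nearest, a gap of 0.865 of the range), of Fkbp5 (gap 0.846), of Tsc22d3 (gap 0.708) and of Per1 (gap 0.804). An array exchanged with that of another culture is argued against by the correlation of 0.731 between the 2 arrays of culture 4, above their highest with any other array (0.686). Noise on an array without a response is argued against by 52 of 55 Dex-responsive genes having the opposite sign in culture 4, with a correlation of -0.890 to the mean of the other cultures. What stays open is that the vehicle and Dex labels of this culture may be exchanged, since with its sign turned its list mean is 0.84, inside the range of the other 12 cultures (0.57 to 0.99). The array labelled vehicle had a list level of 8.95, against 7.94 to 8.52 in the other WT vehicle arrays. That is inside the range of the other WT Dex arrays (8.60 to 9.27). The array labelled Dex stood at 8.11, inside the range of the other WT vehicle arrays. With the culture as a block, exchanging the labels of culture 4 alone took the WT count from 0 to 43 genes. These values go with exchanged labels, but no biological explanation was tested, and no label was changed.

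For the glucocorticoid-induced list the camera test of the difference between genotypes passed, with a mean response larger by 0.33 in SOX2 KO, while camera with an estimated correlation (adjusted p = 0.600), fry (adjusted p = 0.980) and the exact permutation test (p = 0.0927) did not pass. Culture 4 alone accounts for most of it, since without that culture the difference is 0.0725, less than the SD of 0.13 of the SOX2 KO cultures. That the genotype changes the response stays open, because the exact permutation p without culture 4 is 0.307, which does not show that the responses are alike.

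The genes differing between SOX2 KO and WT were weighed against uneven clusters, sex and alleles carried along with the Sox2 locus. With array cluster as a covariate all 109 calls in vehicle and all 110 in Dex passed in the same direction. This covariate did move some genotype differences, such as the mean of the astrocyte list in vehicle, from -0.28 to -0.12. However, the clusters were formed from these same profiles after group means were removed, so they need not match a real batch. That fit therefore does not decide on uneven clusters. With the Eif2s3y level as a covariate 109 and 108 passed in the same direction, which argues against uneven sex as the cause. Sex and cluster overlap, with high Eif2s3y in 4 of 5, 1 of 3 and 0 of 5 cultures of clusters 1, 2 and 3. Chromosome 3 carries Sox2, and 10 of the 109 vehicle calls lie there, Sox2 among them. That argues against alleles acting on genes of this chromosome as the main cause. The count cannot speak to linked alleles that act on genes of other chromosomes. Without Sox2, chromosome 3, with 920 of the 19505 genes, held 9 of 108 calls in vehicle (Fisher's exact two-sided p = 0.103) and 11 of 109 in Dex (exact p = 0.0189). Of the 12 calls there in either comparison other than Sox2, 3 (Anxa5, Pld1 and Zfhx4) are among the 200 measured neighbours of Sox2, which make 21.8% of the chromosome's genes, so for these calls neighbouring alleles and an effect of SOX2 cannot be told apart, the calls being too few.

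The Dex array of SOX2 KO culture 12 stood apart in its lower quartile, at 5.38 against 4.96 for the nearest array of its group (gap 0.712 of the range). Among the 2634 transcript clusters without a gene symbol, 8 passed the threshold in SOX2 KO against WT in vehicle (1 higher, largest log2 fold change 2.64 in size) and 6 in Dex (1 higher, largest 1.96 in size). They are outside the comparisons of named genes.

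Other splits of the arrays were run for each count. For Dex in WT all 100 of 100 splits gave as many genes as the real 0 (highest other 1), and with the culture as a block 32 of 32 did. Any split reaches a count of 0, so these shares decide nothing. With the block, the split that exchanges the labels of culture 4 alone gave 43 and was the only other with calls. With the block and without culture 4 the real count was 33 and the highest other 0, and the 16 splits are too few for a share under 0.05. For Dex in SOX2 KO chance is argued against, at a share under 0.05, with 1 of 100 splits as large (real 10, highest other 1), 1 of 64 with the block (14 and 1) and 1 of 64 with the block and without culture 4 (49 and 7, the latter exchanging culture 12). The 100 splits were drawn without regard to the pairs, while those with the block part every pair. A share of 1 of 64 is the smallest that 64 splits can give. For the difference of the Dex effects all 100 splits gave 0, the real one included, so they decide nothing either.

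For SOX2 KO against WT, 6 of 100 splits gave as many genes in vehicle (real 109, highest other 1710) and 6 of 100 in Dex (real 110, highest other 2582), so chance cannot be excluded from these counts. All 5 other splits keep array cluster 1 or 3 whole, and the largest sets cultures 1, 2, 3, 7, 8 and 9 against the others, so they point to the structure of the clusters. With array cluster as a covariate and splits drawn within clusters, 1 of 100 was as large in vehicle (376 and 9) and 1 of 100 in Dex (397 and 3). The clusters were formed after removing the means of the real groups and were kept for every split. That favours the real labels, so these splits cannot exclude chance either. For the counts of gene lists called by camera, chance cannot be excluded in any comparison. As many lists came from 74 of 100 splits for Dex in WT (real 2, highest other 9), 80 for Dex in SOX2 KO (1 and 12), 10 for the genotypes in vehicle (9 and 11), 10 in Dex (8 and 16) and 71 for the difference of the Dex effects (1 and 10). The 72 genes shared by the genotype comparisons stood against up to 1044 in other splits. With array cluster as a covariate 252 stood against 1, again with clusters formed from the real groups.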

How the results depend on the processing

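The settings with the block and without culture 4, without the Dex array of culture 12 and without cultures 4 and 12, the array cluster and Eif2s3y covariates, the lists without Sox2, and for the fold-change correlation the leaving out of cultures and the 55-gene subset, were chosen after the data were seen. The cause of a change was not tested unless the setting itself names it. No named gene called over all genes in either fit, and no list called by camera, reversed its direction. In the difference of the Dex effects Fam107a went from 1.17 to -0.87 without culture 4, and with the block as well it passed over its list alone. The median of the astrocyte list in vehicle went from -0.14 to 0.07 with array cluster, and some lists called in neither fit changed the sign of their mean, most the oligodendrocyte list in vehicle, from -0.02 to 0.22. A gene whose fold change is smaller than its own SE and called in neither fit was counted as having no direction.

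For Dex in WT the count of 0 became 15 with array weights, 33 with the block and without culture 4, 58 with the block and without cultures 4 and 12, and 9 without these cultures, and leaving out 1 culture gave 0 to 7. It stayed at 0 in the other settings. For Dex in SOX2 KO the count of 10 became 18 with quantile normalization, 28 with array weights, 49 and 66 with the block and without culture 4 or both cultures, 17 without both, and 25 with array cluster, and leaving out 1 culture gave 3 to 16, the 16 without WT culture 4. For SOX2 KO against WT in vehicle the count of 109 became 168 with quantile normalization, 378 with array weights, 164 without the Dex array of culture 12 and 376 with array cluster, and leaving out 1 culture gave 75 to 143. In Dex the count of 110 became 171 with quantile normalization, 72 with the arrays of the 2 groups alone, which are fewer samples, 561 with array weights and 397 with array cluster, and leaving out 1 culture gave 69 to 160. With median centring 43.9% of the vehicle calls and 46.5% of the Dex calls were higher, against 33.9% and 32.7% as deposited. The difference of the Dex effects gave 0 genes in every setting run.

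Gene lists called for Dex in WT went from 2 to 1 with an estimated correlation, 0 with fry, 1 with quantile normalization, 1 with Sox2 left out, 7 with the block and without culture 4, and 6 without cultures 4 and 12. For Dex in SOX2 KO they went from 1 to 3 with the block, 2 with quantile normalization, 4 with the block and without culture 4, and 2 without both cultures. For the genotypes in vehicle 9 lists were called, against 0 with an estimated correlation, 3 with fry (2 of them among the 9) and 3 without both cultures (all among the 9). In Dex 8 were called, against 0, 2 (none among the 8) and 5 (4 among the 8). The 1 list of the difference of the Dex effects became 0 with an estimated correlation, 0 with fry, 0 with the block and without culture 4, and 0 without both cultures. The difference of the glucocorticoid-induced responses (0.33) came under 0.05 before adjustment with the median over the list (0.28, exact p = 0.0437), with quantile normalization (0.39, exact p = 0.0216) and without WT culture 1 (0.40, exact p = 0.0455). Adjusted over the 2 lists only quantile normalization stayed under it (0.0431, against 0.0874 and 0.0909). Leaving out 1 culture gave 0.0725 (without culture 4) to 0.40, and exact p over all these settings lay between 0.0216 and 0.307. For the repressed list it gave -0.09 to -0.01. The Pearson coefficient of the Dex fold changes (0.285) was 0.426 over genes above the median mean, 0.237 with quantile normalization, 0.891 (Spearman 0.612) over the 10 called genes, 0.860 over the 55 genes called with the block and without culture 4, and 0.228 to 0.328 without 1 culture.

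The deposited values give no detection call, so whether a low signal is above background was not tested. The covariate for Xist was not run.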

Other observations

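The lists called with the block and without culture 4 were tested in a fit chosen after the results were seen, and the other values here come from the planned fit. In that block fit, camera called 5 further lists for Dex in WT. The astrocyte list (adjusted p = 0.0330) and the circadian clock list (adjusted p = 0.0261) were higher, the latter with Per1 (2.35 ± 0.18, SE) and Per2 (1.26 ± 0.20) past the threshold over all genes. The immediate early list (adjusted p = 0.00584), the SOX2 network list (adjusted p = 0.00504, with Mycn past the threshold) and the Wnt list (adjusted p = 0.0128) were lower. None of these held with an estimated correlation (adjusted p = 0.281 for the astrocyte, circadian, SOX2 network and Wnt lists and 0.408 for the immediate early list). In SOX2 KO the same fit called the circadian list as higher and the extracellular matrix and replication lists as lower (adjusted p = 0.0306 for each), of which the last 2 also passed with the block and all cultures (adjusted p = 0.0292 for each). With an estimated correlation these had adjusted p of 0.410, 0.410 and 0.563. The Notch modifier gene Lfng rose in both genotypes in this fit, by 0.70 ± 0.13 in WT (adjusted p = 0.0381) and 0.89 ± 0.11 in SOX2 KO (adjusted p = 0.000524).

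Some genes differed between SOX2 KO and WT in lists that did not pass as a whole. In the Wnt list (19 measured, mean 0.01 and median -0.11 in vehicle), Lef1 (1.64 ± 0.37) and the receptor gene Fzd9 (1.13 ± 0.24) were higher and the feedback inhibitor Axin2 (-1.08 ± 0.23) was lower in vehicle. In Dex Lef1 and Fzd9 (1.16 ± 0.24) were higher and no member was lower past the threshold. The laminin gene Lama1 was lower in vehicle (-1.61 ± 0.30) and in Dex (-1.70 ± 0.30), and the versican gene Vcan was higher in Dex (0.97 ± 0.24). The synaptic vesicle gene Syt1 was lower in both (-1.59 ± 0.34 and -1.42 ± 0.34), the only neuronal marker of 26 past the threshold over all genes. Bmp7 was lower in Dex as well (-1.78 ± 0.34). Otx2, from the ependymal and choroid plexus list, was higher in Dex (1.62 ± 0.39, adjusted p = 0.0488). The lists of microglial, endothelial, oligodendrocyte and fibroblast markers passed in no comparison of the planned fit, and none of their members passed over all genes in that fit.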
